A study of Homo sapiens with 24 samples.

How the data were processed

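The authors deposited a table of counts for each library, made from polyadenylated RNA with 50-base read pairs from an Illumina NovaSeq instrument. Per the submitters' processing notes, reads were trimmed with cutadapt, aligned to GRCh38 with STAR 2.6.0c and examined with Picard. Per the file headers, the counts are read pairs per gene from featureCounts 2.1.1 against GENCODE 49, over exons summed by gene and with strand setting 0, so overlapping genes on opposite strands are not separated. Each table held 78691 genes, of which 61458 matched a symbol; the 17233 without one held 0.18% of the counts. Spike-in transcripts are named in the submitters' notes, but the tables hold 0 of them, so no scaling on spike-ins was made. Mitochondrially encoded genes are listed in the tables with 0 reads in every library.

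CPM values, counts scaled to library size, were computed here from the deposited counts with TMM scaling. Genes were tested with edgeR 4.0.16 (filterByExpr, TMM, robust quasi-likelihood F test, 12 group means over 24 libraries, Benjamini-Hochberg adjustment, threshold 0.05), which left 19775 genes, and every adjusted p of a gene is from that test unless DESeq2 1.42.0 is named. Gene lists were tested with camera of limma 3.58.1, with its preset inter-gene correlation of 0.01 and, as an alternative, a correlation estimated from the data, adjusted over the 31 lists with at least 5 tested genes. Other software was R 4.3.3, data.table (version 1.17.8), Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. GC content was known for 17791 of the tested genes (90%).

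GEO's labels give replicate numbers 1 and 2 in every group, and nothing else states a pairing. Over 10432 genes, the difference between replicate 1 and replicate 2 was correlated between groups. Within a line and day, all 12 pairs of groups had r from 0.55 to 0.92, above the threshold of 0.1, and a replicate block of line, day and replicate number was fitted as an alternative. Values above 0.1 were also found between the lines on the same day (18 pairs, 0.24 to 0.52) and between the days of KMS-34 (9 pairs, 0.16 to 0.38), so the replicates share differences beyond a line and day. Between the days of KMS-11, r ran from -0.58 to -0.45, and between lines and days from -0.38 to -0.04. The common biological coefficient of variation was 23.5% without the block (12 residual degrees of freedom) and 6.9% with it (8).

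The pipeline was tested on simulated data built from these libraries, with 50 genes changed at each size. Without the block it recovered 0%, 14%, 34% and 56% of changes of 0.5, 1, 1.5 and 2 on the log2 scale, with 0 false calls among 52. With the block it recovered 26%, 58%, 56% and 68%, with 10 false calls among 114. A list of 22 genes lowered by 0.6 was called, and 0 of 30 unchanged lists were. Counts were drawn independently for each gene and unchanged lists at random. The rate of false calls for lists whose members vary together was therefore not tested. The test of neighbouring genes went beyond all 200 shuffles in 10 of 10 planted sets and in 0 of 40 random sets.

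The genes named in the text were chosen by a rule. NSD2, FGFR3 and CCND2 were named throughout. For each line, genes called in the same direction at 1 uM at both days, with at least 5 CPM in 1 of the compared groups at both days, were named, up to 10 per direction by the smaller of their log2 fold changes, leaving out immunoglobulin and T cell receptor segments and genes known only by clone names. For each list, up to 4 members called at 1 uM on day 14 in either line and up to 2 that did not pass were named. For the differences between lines, doses and days, up to 5 genes per direction were named, and for DMSO between days up to 3. Results for a few individual genes are not reported here.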

Results

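Messenger RNA was sequenced from KMS-11 and KMS-34, human multiple myeloma lines that carry t(4;14). This translocation places NSD2, a histone H3 lysine 36 methyltransferase, and the receptor kinase gene FGFR3 under immunoglobulin heavy chain control. Cells were kept in DMSO, the solvent control, or in 100 nM or 1 uM NSD2-LDD, a compound that degrades the NSD2 protein, for 7 or 14 days. Each of the 12 groups of line, dose and day held 2 libraries, 24 in all. The libraries held 19984097 to 28117454 counted read pairs in KMS-11 and 20525167 to 27969514 in KMS-34. Expression is given as CPM, counts scaled to library size, with the SD over the 2 libraries of a group, and changes as log2 fold changes with their standard error (SE). Nothing in the labels states that replicates came from separate cultures, so the p-values measure only the spread between these samples.

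No change in the transcripts of the translocated genes passed the test, though the test misses most small changes. NSD2 (ENSG00000109685.20, chromosome 4, 1870559 to 1982207, GRCh38) was at 744 ± 90.2 CPM in DMSO and 717 ± 28.1 CPM at 1 uM on day 14 in KMS-11, a log2 fold change of -0.05 (SE 0.19, n = 2 per group). In KMS-34 it was at 1200 ± 148 CPM and 1010 ± 0.275 CPM, a log2 fold change of -0.24 (SE 0.19, adjusted p = 0.77 without the replicate block and 0.058 with it). FGFR3 (ENSG00000068078.21, chromosome 4, 1793286 to 1808873) differed from DMSO by -0.22 to 0.08 over all doses, days and lines, with 2760 ± 282 CPM in KMS-11 and 785 ± 39.3 CPM in KMS-34 in DMSO on day 14. CCND2 (ENSG00000118971.10, chromosome 12, 4269771 to 4306933), a D-type cyclin that drives entry into the cell cycle, was at 595 ± 13.2 CPM in DMSO and 421 ± 8.49 CPM at 1 uM in KMS-34 on day 14, a log2 fold change of -0.50 (SE 0.16). That difference missed the threshold without a replicate block (adjusted p = 0.11) and passed it with one (adjusted p = 0.00016). With the block, CCND2 also passed in KMS-34 at 1 uM on day 7 (-0.47, adjusted p = 0.3 without it and 0.00072 with it), at 100 nM on day 14 (-0.56, 0.13 and 1e-04) and on day 7 (-0.37, 1 and 0.015), and in KMS-11 at 100 nM on day 14 (-0.37, 0.67 and 0.0084). No NSD2 or FGFR3 difference from DMSO passed in either fit, and simulated changes of 0.5 were recovered for 0% of genes without the block and 26% with it. The simulated genes were drawn from all 19775 tested, at any expression level, so the rates for genes expressed as highly as these may differ.

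**Figure D1:**
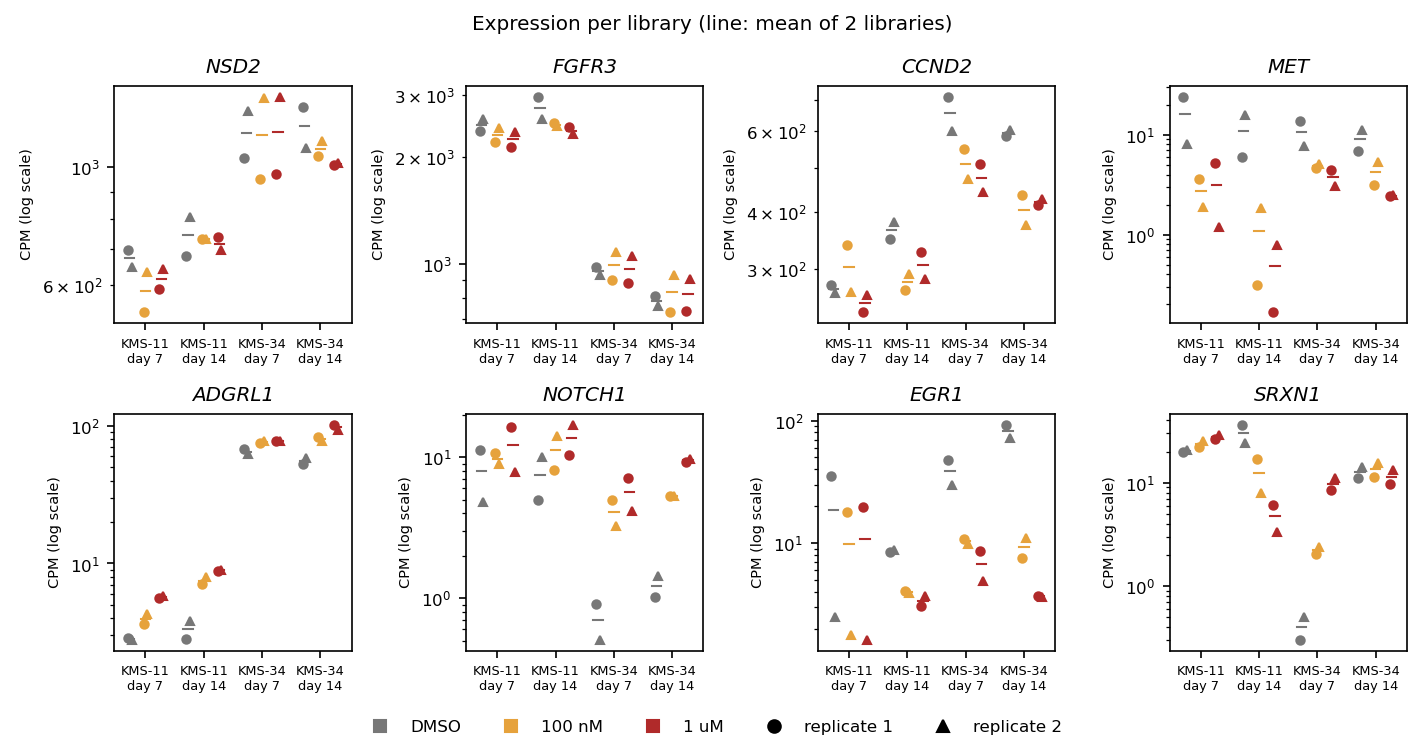
Expression in CPM, on a log scale, of 8 genes in each of the 24 libraries, by line and day on the horizontal axis and by dose in colour; each point is a library, its shape the replicate number, and each line the mean of 2 libraries. NSD2 stayed between 584 and 1200 CPM in every group mean, while NOTCH1 in KMS-34 on day 14 stood at 1.22 CPM in DMSO and 9.48 CPM at 1 uM.

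In KMS-11, few genes were called at 1 uM in the same direction at both days. GPC4 (ENSG00000076716.10, chromosome X, 133300103 to 133416214), a cell surface heparan sulfate proteoglycan, fell from 11 ± 3.68 to 0.727 ± 0.153 CPM on day 14, a log2 fold change of -3.91 (SE 0.42, adjusted p = 5.2e-05), after -2.06 (SE 0.38, adjusted p = 0.041) on day 7. COBL (ENSG00000106078.20, chromosome 7, 51016211 to 51317187), an actin nucleator, fell by 2.00 on the log2 scale on day 7 and by 3.53 on day 14. ZNF704 (ENSG00000164684.13, chromosome 8, 80628451 to 80874781), a zinc finger gene, fell by 1.75 and by 2.72. ADGRL1 (ENSG00000072071.18, chromosome 19, 14147743 to 14206204), an adhesion G protein-coupled receptor, rose from 3.32 ± 0.681 to 8.92 ± 0.146 CPM on day 14, a log2 fold change of 1.43 (SE 0.17, adjusted p = 0.00012), and by 1.01 (SE 0.17, adjusted p = 0.026) on day 7. These were the only genes that met the rule on repeated calls in KMS-11, 1 higher and 3 lower, against 64 and 240 with the replicate block. MET, a receptor tyrosine kinase, stood among the latter, with blocked log2 fold changes of -2.37 on day 7 (adjusted p = 0.63 without the block and 5.4e-07 with it) and -4.55 on day 14 (0.014 and 2.3e-10). So did ANXA1, an annexin, at blocked values of 1.61 and 1.35 (1 and 1 without, 4.9e-09 and 6.4e-08 with).

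Over all genes, 15 differed from DMSO at 1 uM in KMS-11 on day 7, 3 higher and 12 lower, and 267 on day 14, 36 higher and 231 lower. Transcripts restricted to KMS-34 stood at 0.0847% to 0.131% of their KMS-34 level in the KMS-11 libraries with compound on day 14, and at 0.257% to 0.369% in DMSO of that day. This share rests on 9 genes picked as under 0.03 CPM in at least 1 KMS-11 library, a choice that may itself set some libraries low. The day 14 comparison thus crosses a possible library batch, described below, that cannot be told apart from the compound. By trace transcripts, also described below, the 1 uM comparisons of both days do. With the replicate block these counts were 567 (144 higher, 423 lower) and 1695 (415 higher, 1280 lower). Of the 15 on day 7, all named after their values were seen, IGLV3-21, IGHG1, IGHV3-30, IGHG4 and IGLC2, which are immunoglobulin segments, ALB, the albumin gene, SPARC, IRAG2 and NELL2 were lower, and TNNT1 (2.85) and APLP1 (1.96) were higher beside the genes named above. The immunoglobulin segments and IRAG2 were higher again on day 14 (IGHG1: -6.44 on day 7, 6.51 on day 14), and their level also differed between the DMSO groups (IGHG1 at 10.3 CPM on day 7 and 0.0963 CPM on day 14). Without 1 of the 4 libraries compared, the day 7 count was 3 (1 uM replicate 1 left out) to 4 (DMSO replicate 2 left out), and the day 14 count 76 (1 uM replicate 1) to 174 (DMSO replicate 1). GPC4, COBL, ZNF704 and ADGRL1 kept the day 14 call without each of the 4 libraries in turn, and lost the day 7 call, with their direction kept, without any 1 of them (GPC4: -2.70 to -1.61 on day 7). With p adjusted over the genes at 5 CPM or more alone, a filter chosen after the data were seen, 3 passed on day 7 and 144 on day 14. ADGRL1 kept its day 7 call there (adjusted p = 0.042), and GPC4, COBL and ZNF704 lost theirs (adjusted p = 0.054 each).

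In KMS-34, genes of various functions were called at 1 uM at both days. HGF (ENSG00000019991.18, chromosome 7, 81699010 to 81770438), the growth factor that activates MET, rose from 66.7 ± 23.6 to 196 ± 10.9 CPM on day 14, a log2 fold change of 1.55 (SE 0.23, adjusted p = 0.00052), and by 1.34 (SE 0.23, adjusted p = 0.0086) on day 7. NOTCH1 (ENSG00000148400.14, chromosome 9, 136494433 to 136546048), a receptor that sets cell fate, rose by 3.00 on day 7 and by 2.94 on day 14. TLE5 (ENSG00000104964.16, chromosome 19, 3052909 to 3063107), of the Groucho family of co-repressors, rose from 1.22 ± 0.743 to 36.4 ± 9.06 CPM on day 14, a log2 fold change of 4.87 (SE 0.45, adjusted p = 8.9e-06), and by 2.33 on day 7. TNFRSF18, a costimulatory receptor of lymphocytes, rose by 2.62 and 2.67. FAAP20, of the Fanconi anaemia pathway, rose by 2.63 and 3.38, and NME4, a mitochondrial nucleoside diphosphate kinase, by 1.72 and 1.64. The other named genes that rose were the potassium channel gene KCNH2 (1.54 and 1.75), the troponin gene TNNT1 (1.49 and 1.83), the transcription factor gene OSR2 (1.46 and 2.05) and the tetraspanin gene TSPAN4 (1.19 and 1.84).

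Among the genes that fell in KMS-34, PRKAR2B (ENSG00000005249.15, chromosome 7, 107044627 to 107161811), a regulatory subunit of protein kinase A, went from 18.3 ± 2.42 to 2.49 ± 0.165 CPM on day 14, a log2 fold change of -2.88 (SE 0.25, adjusted p = 8.9e-06), after -1.80 (SE 0.23, adjusted p = 0.00065) on day 7. SVIL (ENSG00000197321.17, chromosome 10, 29457332 to 29737123), an actin and membrane linker, fell by 1.89 and by 4.24. ETV5, an ETS factor induced by MAPK signalling, fell by 1.53 and by 1.52. RASAL2, a Ras GTPase-activating protein, fell by 1.62 and by 2.63. IGSF3 (-1.99 and -2.82), RIMKLB (-1.98 and -3.07), DDAH1 (-1.80 and -2.80), UACA (-1.70 and -2.79), WWC3 (-1.54 and -2.40) and CEMIP2 (-1.36 and -1.80) completed the 10 lower genes. Under the rule 12 genes qualified as higher and 25 as lower, against 412 and 545 with the replicate block. EGR1, an immediate early gene of growth factor signalling, passed with the block, going from 82.4 ± 14.9 to 3.69 ± 0.0545 CPM on day 14, with -4.48 (adjusted p = 0.074 without the block and 3.5e-14 with it) and -2.53 on day 7 (0.7 and 4.8e-10). MME, the surface peptidase CD10, had blocked values of -2.54 on day 7 (adjusted p = 0.071 without the block, 4e-06 with it) and -2.40 on day 14 (0.059 and 1.4e-05). The blocked genes named here and for KMS-11 were chosen after the data were examined.

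Over all genes, 113 differed from DMSO at 1 uM in KMS-34 on day 7 (67 higher, 46 lower) and 621 on day 14 (135 higher, 486 lower), of which 563 differed by at least 2-fold. With the replicate block these were 1985 (998 higher, 987 lower) and 4127 (1770 higher, 2357 lower). Of the 67 higher genes on day 7, 19 belonged to 20 genes that were also higher in DMSO on day 14 than in DMSO on day 7, so their call shares the DMSO day 7 libraries with that comparison. Transcripts restricted to KMS-11 stood at 0.0658% to 0.0903% of their KMS-11 level in DMSO and at 0.27% to 0.314% at 1 uM on day 7. This share rests on 14 genes picked as under 0.03 CPM in at least 1 KMS-34 library. The day 7 comparison thus crosses the possible library batch described below. By trace transcripts, also described below, the 1 uM comparisons of both days cross a possible batch. Without 1 library the day 7 count was 27 (DMSO replicate 1) to 41 (1 uM replicate 1), and the day 14 count 290 (1 uM replicate 1) to 388 (DMSO replicate 1). Of the 20 named genes, 18 kept the day 14 call without each library in turn. KCNH2 (1.25) and TNNT1 (1.59) lost it without DMSO replicate 2. On day 7, RIMKLB and PRKAR2B kept the call without each library, and the other 18 lost it without at least 1, with their direction kept. With p adjusted over the genes at 5 CPM or more alone, 73 genes passed on day 7 and 375 on day 14.

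**Figure D2:**
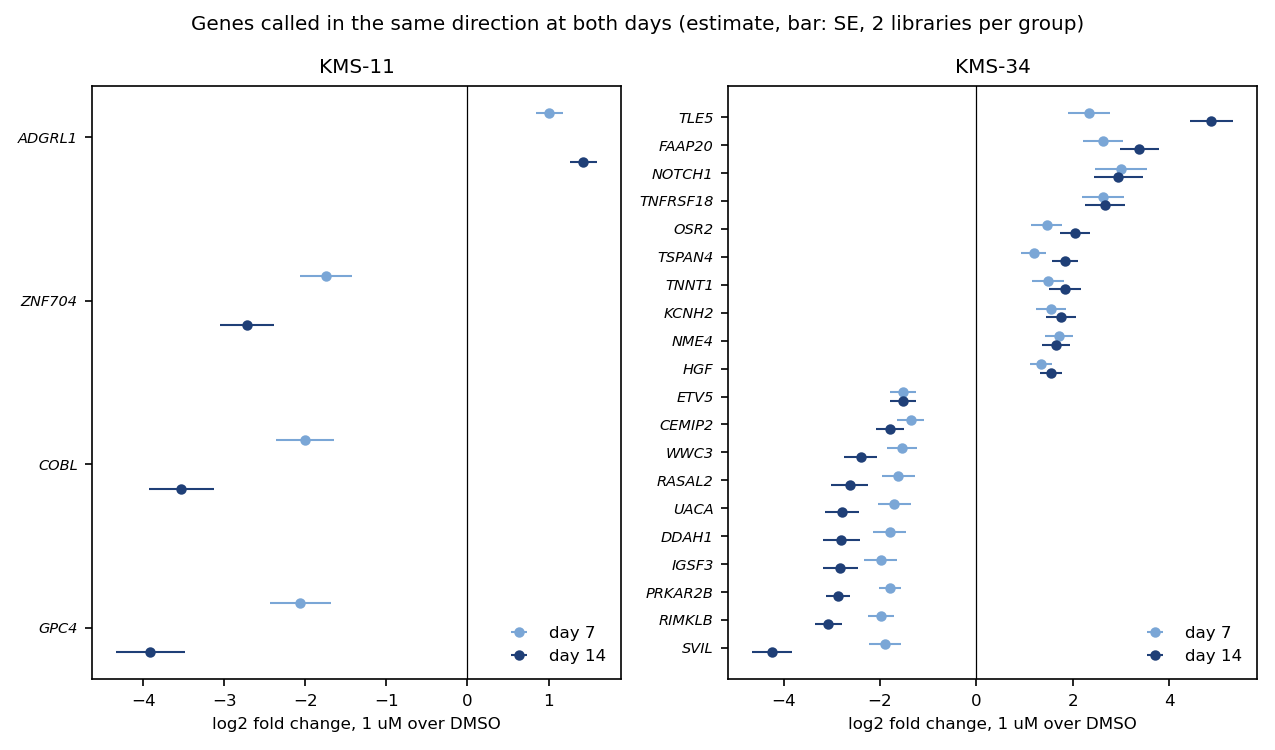
Log2 fold change against DMSO, with bars of 1 SE, of the genes called at 1 uM at both days, with 2 libraries per group, on day 7 and day 14. In KMS-34, TLE5 moved from 2.33 to 4.87 and SVIL from -1.89 to -4.24 between the days.

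At 100 nM the changes were fewer without the block. ALB, at 2.93 CPM or less in KMS-11, was the 1 gene called in KMS-11 on day 7 (-5.92, SE 0.82, adjusted p = 0.016), and 201 genes passed on day 14 (27 higher, 174 lower). That day 14 comparison crosses the possible library batch as well. In KMS-34, 7 genes passed on day 7 and 185 on day 14 (42 higher, 143 lower). The 7, named after their values were seen, were RAB5IF (2.16), TMEM160 (2.72), AGPAT2 (2.44), DNAAF3 and a gene without a symbol (ENSG00000310576.1, 1.88), all higher, and ZNF704 (-2.64) and ITGB5 (-1.14), both lower. Of them, 3 belong to the 20 genes that differed between the DMSO days. With the replicate block the 4 counts were 803 (213 higher, 590 lower), 1389 (373 and 1016), 807 (400 and 407) and 1860 (716 and 1144). Without 1 library, the counts were 0 in each case for KMS-11 on day 7, and 33 (100 nM replicate 1) to 117 (DMSO replicate 1) on day 14. In KMS-34 they were 0 (100 nM replicate 2) to 4 (100 nM replicate 1) on day 7 and 14 (100 nM replicate 1) to 75 (DMSO replicate 2) on day 14.

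**Figure D3:**
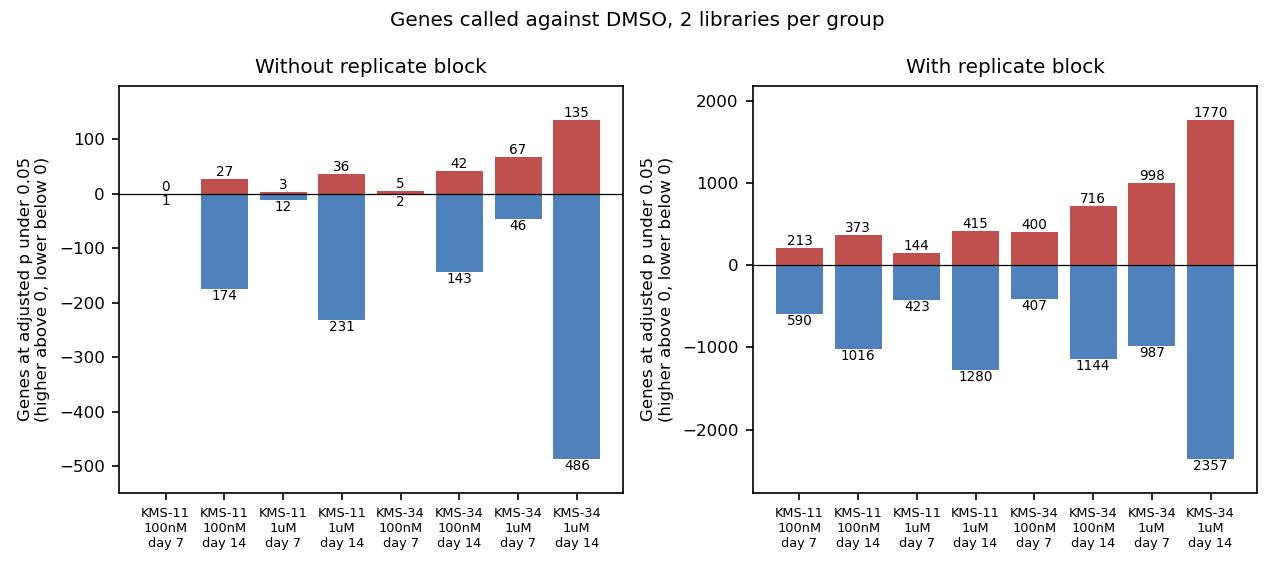
Number of genes at an adjusted p under 0.05 against DMSO in each line, dose and day, higher genes above 0 and lower genes below 0, without the replicate block (left) and with it (right). At 1 uM on day 14 the counts without the block were 267 in KMS-11 and 621 in KMS-34, and with it 1695 and 4127.

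Doses were compared directly at each day. In KMS-11, 3 genes passed on day 7, IGLV3-21, IGHG1 and IGHV3-30, all lower at 1 uM, and 0 on day 14, where 174 had an unadjusted p under 0.05 and DESeq2 called 0. In KMS-34, ALB, KRT8 and IGFBP4, none above 4.72 CPM in any group, were the 3 genes higher at 1 uM on day 7, and 0 passed on day 14, where 611 had an unadjusted p under 0.05 and DESeq2 called 14. These genes fell outside the naming rule and were named after their values were seen. The replicate block gave 13, 5, 64 and 534 genes in the same order. On day 14 in KMS-34 the blocked calls included TLE5 (blocked log2 fold change 1.82, adjusted p = 0.26 without the block and 7.7e-06 with it) and PKIA, a protein kinase A inhibitor (-1.79, 0.059 and 5.3e-09). PRKAR2B was at -1.51 in the same comparison (0.075 and 4.2e-06). Without 1 library the unblocked counts stayed at 3 and 0 in KMS-11, and in KMS-34 were 0 (100 nM replicate 2) to 2 (1 uM replicate 2) on day 7 and 0 on day 14.

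The 22 genes linked to t(4;14) or NSD2, a list fixed with all others before the data were examined, had a median below 0 in every comparison with DMSO. At 1 uM on day 14 their median log2 fold change was -0.23 in KMS-11 (5 lower, 0 higher) and -0.44 in KMS-34 (7 lower, 0 higher). MYRIP, a motor adaptor of secretory granules, fell by 2.84 in KMS-11 (SE 0.56, adjusted p = 0.01) and by 3.08 in KMS-34 (SE 0.58, adjusted p = 0.0039). MET fell by 4.50 in KMS-11 (SE 0.90, adjusted p = 0.014) and was at -1.86 in KMS-34 (adjusted p = 0.3 without the block, 3.8e-06 with it). TGFA, a ligand of the EGF receptor, fell by 1.52 in KMS-11 and was at -0.90 in KMS-34 (adjusted p = 0.18 without the block, 6e-05 with it). ETV5 fell by 1.52 in KMS-34 and was at -0.26 in KMS-11. CDH2 (-1.37 in KMS-11, -0.24 in KMS-34) and TIAM1 (0.92 and -0.01) did not pass, though in KMS-11 both did with the block (adjusted p = 1.9e-10 and 3.8e-05).

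Camera, which tests a list against all other genes, gave the t(4;14) list an adjusted p of 7.5e-06 in KMS-11 and 4.2e-08 in KMS-34 at 1 uM on day 14 (adjusted p = 0.0034 and 0.00095 with an estimated correlation). In KMS-11 on day 14 the compound and DMSO libraries also differed in their share of KMS-34 transcripts (0.0847% to 0.131% and 0.257% to 0.369%), as did the KMS-34 libraries at 1 uM and in DMSO on day 7 in their share of KMS-11 transcripts (0.27% to 0.314% and 0.0658% to 0.0903%). Trace transcripts, described below, differed between 1 uM and DMSO at both days in both lines. On day 7 the medians were -0.13 and -0.26, with 0.00064 and 7.9e-06 (adjusted p = 0.022 and 0.0047 with an estimated correlation). At 100 nM they ran from -0.28 to -0.16, with adjusted p from 2e-05 to 0.0026 (0.0079 to 0.044 with an estimated correlation). With the block and an estimated correlation together, the list passed in KMS-34 at 100 nM on day 14 alone (adjusted p = 0.038), and the calls ended in the other 7 comparisons (adjusted p = 0.055 to 0.2; 0.055 and 0.057 at 1 uM on day 14). Adjusted over the list alone, 7 genes passed in KMS-11 and 9 in KMS-34 at 1 uM on day 14, and 15 and 17 with the block.

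The 25 receptor tyrosine kinase and MAPK feedback genes, which answer growth factor signalling, had medians below 0 in KMS-34. At 1 uM on day 14 their median was -0.96, with 5 lower and 0 higher (adjusted p = 1.6e-08, and adjusted p = 0.011 with an estimated correlation), and 13 lower with the block. With the block and an estimated correlation together that call ended (adjusted p = 0.091). EGR3, an immediate early gene, fell by 4.05 (SE 1.08, adjusted p = 0.046; -5.62 to -1.10 without 1 library, with the call lost in 3 of 4 cases), SPRY2, a feedback inhibitor of receptor kinases, by 2.27 (SE 0.45, adjusted p = 0.006; call lost in 3 of 4 cases) and SPRED1, an inhibitor of Ras signalling, by 1.39 (SE 0.23, adjusted p = 0.0013), beside ETV5. EGR1 and EPHA4 did not pass without the block. On day 7 the median was -0.39 with 2 lower (adjusted p = 0.00051, and adjusted p = 0.13 with an estimated correlation), and at 100 nM on day 14 it was -0.67 (adjusted p = 8e-08, and adjusted p = 0.015 with an estimated correlation, or 0.038 with the block as well). In KMS-11 on day 14 it was -0.42 (adjusted p = 0.097). The difference between the lines had a median of -0.63 on day 14 (adjusted p = 4.4e-05, and adjusted p = 0.13 with an estimated correlation) and -0.43 on day 7 (0.0013, and adjusted p = 0.17 with an estimated correlation). Adjusted over the list alone, 8 genes passed in KMS-34 at 1 uM on day 14, and 17 with the block.

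The 13 MHC class II genes, which present antigen, had a median of -0.92 in KMS-34 at 1 uM on day 14, with 2 lower and 0 higher, or 6 lower with the block. The list had adjusted p = 3.5e-05, a call that ended with an estimated correlation (adjusted p = 0.35). HLA-DRA fell from 20.1 ± 1.41 to 8.03 ± 2.66 CPM, a log2 fold change of -1.32 (SE 0.29, adjusted p = 0.011), and HLA-DPB1 by 1.82 (SE 0.49, adjusted p = 0.049), while HLA-DPA1 (-1.61, adjusted p = 0.059 without the block and 0.003 with it) and HLA-DMB (-1.54) did not pass. In KMS-11 the median was 0.17 (adjusted p = 0.16), and the difference between the lines had a median of -1.18 (adjusted p = 3.4e-09, and adjusted p = 0.13 with an estimated correlation). Adjusted over the list alone, 6 genes passed in KMS-34 and 0 in KMS-11, and 8 and 0 with the block. HLA-DPB1 lost its call without any 1 of the 4 libraries, and HLA-DRA without 1 uM replicate 1 or DMSO replicate 2 (-1.71 to -1.02 over the 4).

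In KMS-34, the ribosomal protein and ER chaperone lists had medians slightly above 0 and the mitosis list below 0, with 0 members called and no list call kept under an estimated correlation. The 65 ribosomal protein genes had a median of 0.37 at 1 uM on day 14 with 0 called (adjusted p = 7.8e-11, and adjusted p = 0.69 with an estimated correlation). With the block 61 were higher, and the median was 0.32 after correction for GC content and length. RPL26 (0.64) and RPS29 (0.55) were the named members that did not pass. The 22 ER chaperone genes had a median of 0.22 (adjusted p = 0.0011, and adjusted p = 0.66 with an estimated correlation) and 0 calls, or 13 higher and 1 lower with the block. SEL1L was at 0.57 and CRELD2 at 0.51. The 31 mitosis genes had a median of -0.26 (adjusted p = 0.0015, and adjusted p = 0.73 with an estimated correlation) and 0 calls, or 20 lower with the block. MKI67 was at -0.60 and CENPE at -0.59. In KMS-11 the ribosomal, ER and mitosis medians were 0.02, -0.01 and 0.04 (adjusted p = 0.82, 0.89 and 0.48). The 7 tested cancer-testis antigens, at most 1.38 CPM in any group for the 6 examined singly, had adjusted p = 3.5e-06 (adjusted p = 0.24 with an estimated correlation), and their level also differed between the DMSO groups of KMS-34 (median 0.401 CPM on day 7 and 0.01 CPM on day 14). Over all 31 lists tested, camera called 1 in KMS-11 and 7 in KMS-34 at 1 uM on day 14, and 5 and 11 with the block. With an estimated correlation these were 1 and 2, and 0 and 0 with the block as well.

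Several lists held changed genes without passing as a group at 1 uM on day 14. JCHAIN, which joins polymeric immunoglobulins, rose in KMS-34 from 29.9 ± 7.27 to 157 ± 38.8 CPM, a log2 fold change of 2.39 (SE 0.30, adjusted p = 0.00012), in a plasma cell list with adjusted p = 0.59. Of 36 adhesion and matrix genes, the integrins ITGB2 (3.94) and ITGA8 (2.19) rose and 4 fell in KMS-34, among them fibronectin, FN1 (-2.48), and NCAM1 fell by 2.30 in KMS-11 (list adjusted p = 0.32 in KMS-34 and 0.48 in KMS-11). Of 23 B cell genes, SYK (-5.50), CR2 (-1.35) and PLCG2 (-0.84), parts or partners of B cell receptor signalling, fell in KMS-34 (list adjusted p = 0.52). Of 36 interferon response genes 4 rose and 2 fell in KMS-34, with IFITM1 at 1.70, IFITM2 at 2.05, LGALS3BP at 2.04 and HERC5 at -1.99 (list adjusted p = 0.98). The list of 10 MAF-associated genes had adjusted p = 0.16 in KMS-11. In KMS-34 its median was -0.70 (adjusted p = 0.073 without the block and 0.0095 with it, and adjusted p = 0.15 with an estimated correlation and the block). Of 31 cytokine and chemokine receptors, IL4R fell by 2.01 and TGFBR1 by 0.88 in KMS-34, beside the rise of TNFRSF18 (list adjusted p = 0.74). SESN1, a p53 target, rose by 1.18 in KMS-34 (list adjusted p = 0.88). Of 40 developmental and homeobox genes, NKX2-1 fell by 2.19 and TBX3 by 2.46 in KMS-34 (list adjusted p = 0.75). HOXC8 and HOXC6 were listed at 0 in both DMSO libraries and reached 1.09 ± 0.449 and 1.01 ± 0.206 CPM. Of the 22 cholesterol synthesis genes 0 passed in KMS-11 and 11 were lower with the block (median -0.36, adjusted p = 0.082 without the block and 1.5e-11 with it, and adjusted p = 0.11 with an estimated correlation and the block). COL6A1, a collagen VI chain, rose by 3.39 in KMS-11, where the list of 9 stromal markers had adjusted p = 0.48. Of the called list members at this dose and day, 9 of 27 in KMS-34, among them JCHAIN, SYK, FN1, ITGA8, HERC5, NKX2-1, ETV5, SPRED1 and TNFRSF18, and 0 of 7 in KMS-11 kept the call without each of the 4 libraries in turn.

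The other lists did not pass at 1 uM on day 14. Their adjusted p in KMS-11 and KMS-34 were 0.85 and 0.35 for MHC class I presentation, 0.16 and 0.76 for DNA replication, 0.93 and 0.44 for D cyclins and CDK inhibitors, 0.96 and 0.32 for MYC and ribosome biogenesis, and 0.93 and 0.13 for the BCL2 family. They were 0.96 and 0.76 for the integrated stress response, 0.93 and 0.92 for the H3K36 and H3K27 methylation machinery, 0.93 and 0.63 for NF-kB targets, 0.93 and 0.98 for glycolysis and hypoxia, and 0.96 and 0.12 for oxidative phosphorylation. They were 0.82 and 0.75 for E3 ligase components and cereblon substrates, 0.96 and 0.74 for heat shock, 0.052 and 1 for erythroid markers and 0.78 and 0.59 for replication-dependent histones. At 100 nM on day 14 in KMS-34, 9 lists were called. Beside the t(4;14) and receptor kinase lists, MHC class II (median -1.17, adjusted p = 7e-11, and adjusted p = 0.064 with an estimated correlation), the MAF list (-0.56, adjusted p = 0.011, and adjusted p = 0.064 with an estimated correlation), NF-kB targets (-0.29, adjusted p = 0.029, and adjusted p = 0.42 with an estimated correlation) and MHC class I (-0.14, adjusted p = 0.029, and adjusted p = 0.56 with an estimated correlation) were lower. The ER chaperone list (0.20, adjusted p = 0.0065, and adjusted p = 0.56 with an estimated correlation), the ribosomal list (0.22, adjusted p = 2.8e-06, and adjusted p = 0.77 with an estimated correlation) and the cancer-testis list (adjusted p = 1.4e-07, and adjusted p = 0.093 with an estimated correlation) were higher. With the block and an estimated correlation together, the t(4;14), receptor kinase, MAF, MHC class II and NF-kB lists passed, each at adjusted p = 0.038. T and NK cell markers (4 tested) and myeloid markers (2 tested) were too few to test, and mitochondrially encoded mRNAs had 0 members tested.

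**Figure D4:**
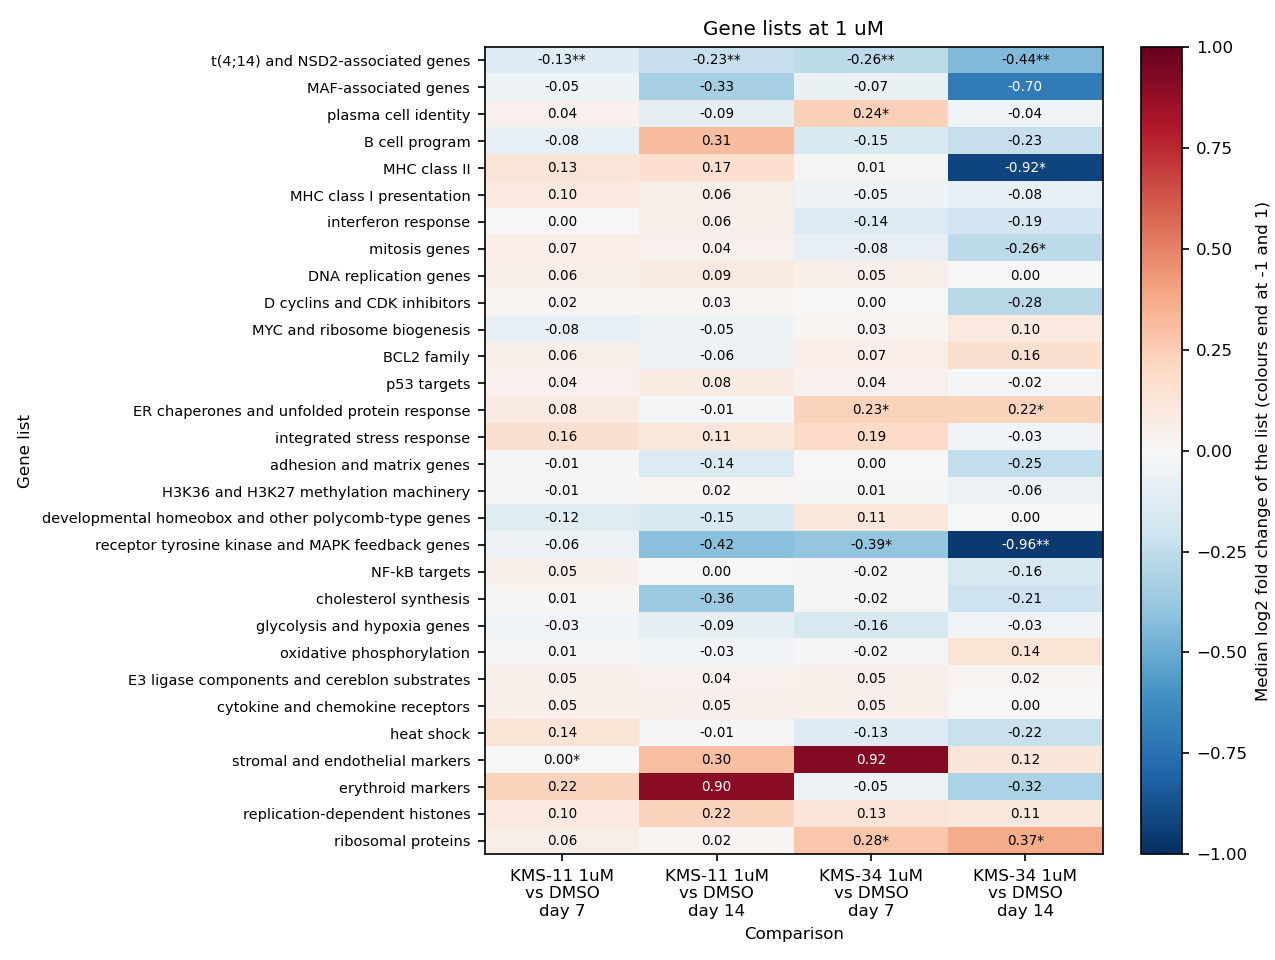
Median log2 fold change against DMSO of each gene list, shown as colour by comparison and list, with 1 star where camera gave an adjusted p under 0.05 and a second star where it also did with an estimated correlation. The t(4;14) list at 1 uM on day 14 stood at -0.23 in KMS-11 and -0.44 in KMS-34, and the receptor tyrosine kinase list in KMS-34 at -0.96.

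The lines were compared by the test of the difference between their 1 uM effects. AGPAT2 (ENSG00000169692.15, chromosome 9, 136673142 to 136687457), an enzyme of phosphatidic acid synthesis, rose in KMS-34 from 0.753 to 13.2 CPM on day 14 and stayed at 81.3 and 85.5 CPM in KMS-11. The difference was 4.03 (SE 0.47, adjusted p = 0.00021), after 3.24 (SE 0.50, adjusted p = 0.0066) on day 7. SRXN1 (chromosome 20, 646615 to 653378), a repair enzyme of peroxiredoxins, differed by 4.14 on day 7 and 2.55 on day 14, and C4orf48 by 2.51 and 2.11. On day 7 both rose in KMS-34 (SRXN1: 4.58, against 0.44 in KMS-11; C4orf48: 2.80 and 0.30). On day 14 both fell in KMS-11 (SRXN1: -2.68, against -0.14 in KMS-34; C4orf48: -1.83 and 0.27). SRXN1 and C4orf48 belong to the genes that also differed between the DMSO days in KMS-34. In all, 27 genes differed on day 7, 27 of them higher in KMS-34, and 85 on day 14 (36 higher, 49 lower), against 447 (267 and 180) and 1663 (773 and 890) with the replicate block. Of the 27 on day 7, 7 belong to the genes that differed between the DMSO days in KMS-34 and 5 are immunoglobulin segments. The others except AGPAT2, such as ALB, KRT8, CTSL and MGST1, named after their values were seen, stayed at or below 2.93 CPM in all groups of at least 1 of the lines. The 3 genes named differed at both days, and 149 higher and 133 lower did with the block. Without 1 of the 8 libraries the counts were 10 (KMS-11 1 uM replicate 2) to 17 (KMS-11 1 uM replicate 1) on day 7 and 25 (KMS-34 1 uM replicate 2) to 58 (KMS-11 1 uM replicate 1) on day 14. AGPAT2 on day 14 and SRXN1 on day 7 passed without each of the 8. AGPAT2 on day 7 lost its call without KMS-34 DMSO replicate 2, and SRXN1 on day 14 and C4orf48 at both days lost theirs without 5 or 7 of them.

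Calls were shared between days and lines beyond the number expected if they fell on genes at random. In KMS-34, 26 genes were higher and 42 lower at 1 uM on both days, where 0.457 and 1.13 were expected, and 0 went opposite ways. Between the lines on day 14, 12 were higher and 95 lower in both, where 0.246 and 5.68 were expected, and 0 went opposite ways. On day 7, 1 was higher, 1 lower and 1 opposite. In KMS-11, 3 were higher and 4 lower on both days, and 6 went opposite ways, 5 of them immunoglobulin genes. With the block the genes shared in direction were 1315, 798, 260 and 447, and 80 went opposite ways between the lines on day 14. The random expectation treats genes as independent, which they are not.

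The effect of 1 uM was also compared between days, and DMSO between days. LAIR1 (chromosome 19, 54351384 to 54370558), an inhibitory immune receptor, rose from 0.385 to 9.06 CPM on day 14 in KMS-11, and its effect was larger on day 14 than on day 7 by 3.59 (SE 0.47, adjusted p = 0.001). SRXN1 (-3.12) and CRLS1 (-3.05), the cardiolipin synthase, had lower effects on day 14 in KMS-11, where 10 genes differed (8 higher, 2 lower; 142 with the block). The higher genes beside LAIR1 were 5 immunoglobulin segments, IRAG2 and SMOC1, named after their values were seen, and both lower genes belong to those that differed between the DMSO days in KMS-34. In KMS-34, 10 differed as well (4 higher, 6 lower), or 492 with the block. Of the 6 lower genes, 5 were among the genes that differed between the DMSO days. So were the higher genes EVC and LSP1, named after their values were seen (7.7 and 6, against -5.97 and -3.55 in DMSO). In KMS-34 EVC stayed at or below 0.323 CPM in every group, and LSP1 at or below 3.51 CPM. In DMSO on day 14 they were at 0 and 0.0793 CPM, so these log2 values rest on counts near 0. SRXN1 was at -4.72, RAB5IF at -3.31, TMEM160 at -2.95, BASP1, a neuronal membrane protein gene, at -2.76 and C4orf48 at -2.53. BASP1 went from 23.9 to 1.61 CPM at 1 uM on day 14. In DMSO, 5 genes differed between the days in KMS-11, IGLV3-21, IGHG1, IGHV3-30, SPARC and IGHG4, named after their values were seen and all lower on day 14, and 22 in KMS-34 (20 higher, 2 lower; 47 with the block), the higher ones including SRXN1 (0.403 ± 0.144 to 12.5 ± 2.17 CPM, 4.93, SE 0.44, adjusted p = 1.1e-05), RAB5IF (3.27) and TMEM160 (2.99). Without 1 library the counts were 7 (DMSO day 7 replicate 2) to 11 (1 uM day 14 replicate 1) and 3 (DMSO day 7 replicate 2) to 7 (DMSO day 7 replicate 1) for the effects, and 3 in every case for DMSO in KMS-11 and 5 (day 7 replicate 2) to 12 (day 14 replicate 1) in KMS-34. LAIR1, and SRXN1 and RAB5IF in KMS-34, passed without each library. SRXN1 and CRLS1 in KMS-11 lost the call without 4 of the 8, TMEM160 in KMS-34 without 7 and BASP1 and C4orf48 without any 1. TMEM160 in DMSO lost it without day 7 replicate 1 (2.70).

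**Figure D5:**
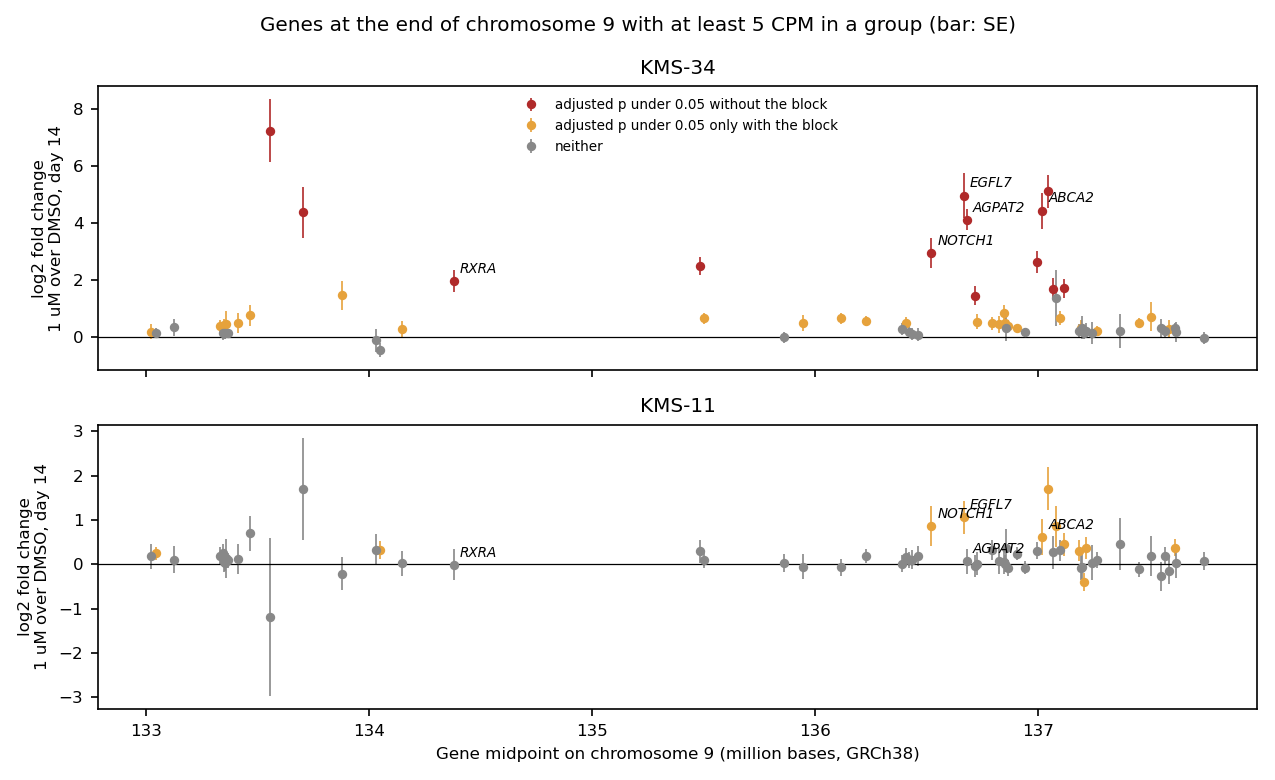
Log2 fold change at 1 uM on day 14 of genes at 5 CPM or more near the end of the long arm of chromosome 9, by position in megabases, in KMS-34 and KMS-11; each point is a gene, red where it passed the test without the replicate block and yellow where it passed with it alone. In this region of 103 genes with a mean of at least 1 CPM in a group, chosen after the data were seen, 27 were higher in KMS-34 and 2 in KMS-11.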

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

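All tests of the trace transcripts and of the genes that differ between the KMS-34 DMSO groups were chosen after the result was seen. The tests of GC content and expression, of neighbouring genes that fell without the compound and of chromosome ends were written before theirs, and the other tests of neighbouring genes after.

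Results drew a closer look where the 1 uM effect differed between the lines or between the days by a test of that difference. Between the lines, 27 genes differed on day 7 and 85 on day 14, with AGPAT2 at 3.24 and 4.03, SRXN1 at 4.14 and 2.55 and C4orf48 at 2.51 and 2.11. Between the days, 10 genes differed in KMS-11, with LAIR1 at 3.59, SRXN1 at -3.12 and CRLS1 at -3.05, and 10 in KMS-34, with SRXN1 at -4.72, RAB5IF at -3.31, TMEM160 at -2.95, BASP1 at -2.76 and C4orf48 at -2.53.

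Immunoglobulin, plasma protein and cancer-testis transcripts at trace level were present in some groups and absent in others. ALB, a plasma protein made by the liver, was at 2.93 CPM in KMS-11 DMSO and 3.16 CPM in KMS-34 1 uM on day 7 and at most 0.275 CPM elsewhere, and IGHG1 in KMS-11 went from 10.3 CPM to 0.0963 CPM between the DMSO days. The compound alone is argued against, since all 6 cancer-testis antigens were lower in both KMS-34 DMSO day 14 libraries than in both day 7 libraries. Carry-over from libraries of the other line alone is argued against for IGHG1, IGLV3-21, IRAG2 and IGHG4 in KMS-11. Transcripts restricted to the other line reached at most 0.369% of their level there. They were picked as under 0.03 CPM in at least 1 library, so their choice may set that share low. All 14 transcripts examined lay above it in both libraries of their highest group. For those named it gives 0.249, 0.112, 0.0764 and 0.0452 CPM, against group means of 10.3, 14.7, 0.803 and 1.41 CPM. For the others it gives at most 0.0124 CPM, less than 1 read at this depth, so the test cannot decide there. Carry-over from libraries outside this series may contribute, since the antigens in KMS-34 and immunoglobulins in KMS-11 matched in presence in 6 of 6 dose and day groups. That match holds for this pairing only. In KMS-11 the antigens were present in every group, with medians of 0.207 to 0.703 CPM (0.703 CPM at 1 uM on day 7). ALB followed neither the antigens in KMS-34 nor the immunoglobulins in KMS-11. No biological explanation was tested for these transcripts.

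The second pattern holds 20 genes, SRXN1, RAB5IF, TMEM160, C4orf48 and CRLS1 among them, higher in KMS-34 DMSO on day 14 than on day 7. Of these, 10 fell in KMS-11 at 1 uM on day 14, where 0.234 were expected if genes were independent, which they are not. The compound alone cannot give a difference between DMSO groups, by which the genes were picked, so the overlap is no separate test of it. The same 10 fell against DMSO of the same day, which argues against time in culture alone. Their median there, -1 over the 19 with a known GC content, lay below all 10000 lists matched on GC content, length and expression (lowest -0.37), which argues against those properties. Library batches may explain part of this. The groups with the lowest share of the other line's transcripts (0.0658% to 0.131%, against 0.192% to 0.369% elsewhere) held the low values. These shares rest on 9 genes in KMS-11 libraries and 14 in KMS-34 libraries. They were picked as under 0.03 CPM in at least 1 library, which may set some libraries low. In KMS-11, 16 of the 20 genes lay below all 4 other groups in both groups of low share. Chance gives 1.33 of 20, and 20.1% of 10642 genes did so. Those groups are 100 nM and 1 uM on day 14, where 10 of the 20 were already called lower at 1 uM. The count is therefore not separate support. In KMS-34 the groups of low share were 100 nM and DMSO on day 7. There 100 nM was higher than DMSO by a median of 1.18 over the 20 genes (3 called higher, 17 with the block). A batch marked by that share alone does not give this difference. Several comparisons set low-share against other libraries and so cross this possible batch. In KMS-11 these are 100 nM and 1 uM against DMSO on day 14 (201 and 267 genes). In KMS-34 they are 1 uM against DMSO and against 100 nM on day 7 (113 and 3) and DMSO between days (22). The differences of the 1 uM effect between days (10 and 10) and between lines (27 and 85) cross it as well. Trace transcripts mark another grouping, of 1 uM on day 7 and DMSO on day 14. In KMS-34 these groups were low in cancer-testis antigens (medians of 0.029 and 0.01 CPM, against 0.384 to 0.619 CPM elsewhere). In KMS-11 they were low in immunoglobulin transcripts (IGHG1 at 0.114 and 0.0963 CPM, against 8.22 to 10.3 CPM elsewhere). By this marker, 1 uM against DMSO crosses a possible batch at both days in both lines, and 100 nM against DMSO on day 14. No label gives a batch, and such a batch and the groups cannot be told apart.

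The third pattern is that neighbouring genes changed together at 1 uM on day 14, tested among the 15731 genes with a mean of at least 1 CPM in a group, which hold 129 of the 135 genes that rose in KMS-34 and 34 of 36 in KMS-11. In KMS-34, 31 adjacent pairs at least 1000 bases apart both fell, above the highest of 1000 shuffles over all genes (21), which argues against reads shared by overlapping genes. It was also above the highest within classes of GC content and expression (23), which argues against those as the whole cause. Among as many genes, the largest differences between the DMSO replicates gave 24 and 10 pairs by direction, so for genes that fell, neighbours that vary together without the compound cannot be told apart from an effect of it. In KMS-11 they gave 6 and 5, against 12 for the genes that fell. For the 129 genes that rose in KMS-34, with 24 pairs (highest shuffle 5), the DMSO replicates gave at most 5, which argues against that explanation there. Runs of up to 5 such genes (RXRA to PIERCE1) lay in the chromosome 9 region described below. Runs of 2 genes that rose also lay on other chromosomes, such as FAAP20 and SKI, JAG2 and NUDT14, and MAPK12 and MAPK11. Pairs at least 1000 bases apart were not counted without chromosome 9, so the count may still rest largely on 1 region. A change of chromosomal regions with the compound may add to this, since KMS-11 had 12 pairs that fell (highest shuffle 9), though that comparison crosses the possible batch. The 34 genes that rose in KMS-11 formed 1 pair (highest shuffle 2). With the block, 396 genes that rose formed 33 pairs (highest shuffle 15) and 1248 that fell formed 141 (highest shuffle 91). Genes that rose lay near chromosome ends in KMS-34 (82 of 129 within 5 megabases, highest shuffle 53), and in KMS-11 17 of 34 did (highest shuffle 18). With the block, 96 of 396 did in KMS-11 (highest shuffle 92). Leaving chromosome 9 out turned both KMS-11 outcomes, to 15 of 32 without the block (highest shuffle 14) and 82 of 372 with it (highest shuffle 83). Whether both lines share it stays open, since these outcomes differ and the KMS-11 comparison crosses the possible batch.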

How the results depend on the processing

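The settings restricted to 5 CPM, GC and length offsets, crossed pairing, the block beside a second change and the block for lists and overlaps were tests chosen after seeing the data. Of the 1019 values of named genes, 0 changed sign under any setting where either of the compared fits called them. Changes of sign among values called in neither fit were not counted. With RLE size factors 1017 kept their side of the threshold, without a filter 947, with the replicate block 712 and with DESeq2 971. With libraries of the same line only 876 of 925 did, and with GC and length offsets 898 of 914. All 18 counts of genes stayed within 1.5 times with RLE size factors. Genes called without the block were all called with it. Crossed pairing of KMS-11 DMSO day 14 with day 7 called 7 genes, against 6 with the replicate block. What the depth of 19984097 to 28117454 read pairs limits was not tested. With 2 libraries per group, changes of 0.5 were recovered in 0% of simulated genes without the block and in 26% with it. Scaling on spike-ins was not run, since the tables hold 0 of them. For the changes below the cause was not tested, except where fewer genes or libraries entered by construction.

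Counts of genes against DMSO in the order KMS-11 100 nM day 7, day 14, 1 uM day 7, day 14, then KMS-34 alike, were 803, 1389, 567, 1695, 807, 1860, 1985 and 4127 with the replicate block. For 1 uM against 100 nM it gave 13 and 5 in KMS-11 and 64 and 534 in KMS-34, for the day difference of the effect 142 and 492, for DMSO between days 47 in KMS-34, and for the line difference 447 and 1663. It gave 8, 4, 7 and 5 lists called in KMS-11 and 11 in KMS-34 at 1 uM on day 14, all 0 with an estimated correlation as well, and 447, 1315, 260 and 798 genes shared in direction between the days of KMS-11, the days of KMS-34, and the lines on day 7 and on day 14.

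With no filter beyond 1 count, the counts were 60, 310 and 78 for KMS-11 100 nM day 7, day 14 and 1 uM day 7, and 75, 334 and 251 for KMS-34. They were 9 for 1 uM against 100 nM in KMS-11 on day 7, 20 and 19 in KMS-34 on days 7 and 14, 17 and 43 for the day difference, 14 and 44 for DMSO between days, and 68 and 185 for the line difference. With DESeq2 they were 37 and 56 for KMS-11 100 nM and 1 uM on day 7, 61 and 302 for KMS-34 100 nM on days 7 and 14, and 260 for 1 uM on day 7. DESeq2 gave 6 and 14 for 1 uM against 100 nM in KMS-34, 18 and 35 for the day difference, 42 for DMSO between days in KMS-34 and 167 for the line difference on day 14.

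With libraries of the same line only, which leaves fewer libraries to estimate the spread, the counts were 0, 99, 3 and 150 in KMS-11, 90 for KMS-34 100 nM day 14, 63 for 1 uM day 7, 6 for 1 uM against 100 nM in KMS-34 on day 7, 4 for the day difference and 2 for DMSO between days in KMS-11. With only genes with a mean CPM of at least 5, so fewer genes, they were 0, 97, 3 and 144 in KMS-11, 88 for KMS-34 100 nM day 14, 73 and 375 for 1 uM, 0 and 2 for 1 uM against 100 nM in KMS-34, 5 for the day difference and 2 for DMSO between days in KMS-11, and 15 for the line difference on day 7. GC and length offsets gave 11 for KMS-34 100 nM day 7. With an estimated correlation, lists called were 1 and 1 in KMS-11 on day 7 at 100 nM and 1 uM, and in KMS-34 1 and 2 at 100 nM and 1 and 2 at 1 uM. With the block and libraries of the same line only, the counts were 1517 and 853 for KMS-11 100 nM and 1 uM on day 7 and 437 for KMS-34 100 nM on day 7, and with the block and DESeq2 351 for KMS-11 1 uM on day 7.

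Without 1 library in turn, where the lone library of an arm is assumed to vary like the other groups, the lowest and highest counts in the same order were 0 and 0, 33 and 117, 3 and 4, 76 and 174 in KMS-11, and 0 and 4, 14 and 75, 27 and 41, 290 and 388 in KMS-34. They were 3 and 3, 0 and 0 (KMS-11) and 0 and 2, 0 and 0 (KMS-34) for 1 uM against 100 nM, 7 and 11 and 3 and 7 for the day difference, 3 and 3 and 5 and 12 for DMSO between days, and 10 and 17 and 25 and 58 for the line difference. With the block they were 95 and 1052, 544 and 708, 157 and 229, 730 and 908 in KMS-11, and 168 and 462, 692 and 1741, 837 and 1319, 2954 and 3434 in KMS-34.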

Other observations

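The tests of genes in 1 region of chromosome 9 were chosen after the result was seen. Between 133019486 and 138197973 on chromosome 9, 27 of 103 genes with a mean of at least 1 CPM in a group rose in KMS-34 at 1 uM on day 14 and 0 fell, with a median log2 fold change of 0.66, against 5 and 0 on day 7 (median 0.28). In KMS-11, 2 rose on day 14 (median 0.19) and 0 on day 7 (median 0.10). With the replicate block, 58 rose on day 14 and 31 on day 7 in KMS-34, and 15 (1 fell) and 5 in KMS-11. RXRA, a retinoid receptor gene (1.95), EGFL7, a secreted vessel factor gene (4.95), ABCA2, a lipid transporter gene (4.42), and DPP7, a lysosomal peptidase gene (1.71), rose in KMS-34, chosen after their values were seen. Many of the 27 stayed below 5 CPM in every group of both lines, such as MYMK (at most 2.39 CPM), OBP2A (3.24), PAEP (2.77), SOHLH1 (1.2) and GPSM1 (4.08). NOTCH1 and AGPAT2 lie in this region. Leaving chromosome 9 out, 55 of 102 such genes that rose in KMS-34 lay within 5 megabases of a chromosome end, against a mean of 25.6 and at most 38 in 1000 shuffles within classes of GC content and expression. In KMS-11, 15 of 32 did (highest shuffle 14), and 82 of 372 with the block (highest shuffle 83).

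Genes that rose were richer in GC than genes that fell. The median GC content was 61.4% for genes that rose and 45.6% for genes that fell in KMS-34 at 1 uM on day 14, 58.8% and 45.8% in KMS-11, and 48.1% for all genes tested. After correction for GC content and length, 590 genes were called in KMS-34 at 1 uM on day 14, 542 of them among the 621 called before. With the block, 1287 of the 1770 higher genes and 2062 of the 2357 lower genes kept their call. Replicate 2 at 1 uM of that line and day had the strongest such trend of the 24 libraries (Spearman rho 0.17 with GC content and -0.21 with length).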
